A study of Homo sapiens with 24 samples.

How the data were processed

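RNA levels were measured in 24 libraries of H929 and MM1S, established human multiple myeloma cell lines, treated with the vehicle DMSO or with YKL-5-124, a compound known by this code name and directed at the kinase CDK7 according to the series title (YKL below). Cells were collected after 6 h or 24 h, which gave 8 groups of 3 libraries. The dose on the labels was 83 nM for H929 and 98 nM for MM1S, and the same figure stands on the DMSO labels, so line and dose could not be separated. Group and replicate number were taken from the labels. The labels did not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

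Per the labels' protocols, total RNA was extracted from lysed cells and made into libraries that read the 3′ ends of polyadenylated transcripts (QuantSeq). Reads were processed with HISAT2 and Cuffnorm against hg19, per the submitters' processing notes, which gave no versions. The authors deposited 1 table of FPKM per library with 26341 entries, of which 92 were ERCC spike-in transcripts and 26249 were genes. FPKM divides by gene length, which is not suited to 3′ end reads. The division is the same in every library and drops out of a ratio of FPKM of a gene between groups. It does not drop out of the filter at 1 FPKM, of log2(FPKM + 1) or of sums over genes. No value was 0. Genes with no signal held small values near 0.1 FPKM that differed between libraries and between genes, with library minima from 0.037 to 0.137 FPKM. In H929 DMSO 6 h replicate 1, the only library in which this was counted, 5638 of the 26341 entries shared the most common value. The 50 ERCC transcripts with a mean of at least 10 FPKM were nearly level across libraries, with median deviations of -0.042 to 0.09 on the log2 scale, as after scaling to the spike-ins. The SD of these deviations was 0.155 to 0.329 in most libraries, but 0.964 in MM1S YKL 6 h replicate 2 and 0.58 in MM1S DMSO 24 h replicate 1, where the deposited scale is less certain. That scaling was not given in the sources used here. On such a scale a change in the RNA of the whole library moves every gene, and an unequal amount of cells or spike-in does the same. No read counts could be recovered, so the sequencing depth is unknown and no counting interval is given. No pair of libraries was identical, and no per-sample column was left unused (0).

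Genes were tested with limma 3.58.1 in R 4.3.3 (limma-trend, two-sided) on log2(FPKM + 1), over the 12418 genes with at least 1 FPKM in at least 3 libraries. All 24 libraries entered 1 fit with 8 group means. Adjusted p-values are Benjamini-Hochberg values within a comparison, with a threshold of 0.05. A fold change on the log2(FPKM + 1) scale understates the change of low genes. Since the deposited values carry the whole-library scale, each result is also given after median-of-ratios rescaling (reference genes with a geometric mean of at least 5 FPKM), called rescaled below. The deposited scale is the main one. Errors of log2 changes are standard errors and errors of FPKM are SDs of 3 libraries.

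The 11 comparisons were YKL against DMSO in each line at each time, the difference of these responses between lines at each time and between times in each line (interactions), and H929 against MM1S and 24 h against 6 h among the DMSO libraries. Before the data were examined, the design, the alternatives, 27 gene lists and the rule for named genes were fixed. The rule took, per YKL comparison, the 6 largest rises and 6 largest falls among called genes with no overlap between the groups, up to 3 members with the smallest p of at most 8 lists, and always CDK7, MYC, IRF4, MCL1, E2F1, CDKN1A, CCND2 and XBP1. In the other comparisons it took the 3 largest values of each sign. LOC genes and small RNA classes with fixed prefixes were left out. Genes chosen after their values were seen are named as such.

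The 22 lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and fry as alternatives. They were replication and G1/S, G2/M and mitosis, homologous recombination and Fanconi anaemia, p53 targets, MYC targets and ribosome biogenesis, cytosolic ribosomal proteins, myeloma regulators, plasma cell surface, unfolded protein response, ATF4 and amino acid response, immediate early genes, NF-kB targets, BCL2 and IAP families, interferon-stimulated genes, cholesterol synthesis, glycolysis and hypoxia, nuclear genes of oxidative phosphorylation, CDK7 with TFIIH and transcription kinases, cell cycle CDKs and their inhibitors, replication-dependent histones, heat shock and markers of MM1S. The other lists were markers of H929 (3 measured), of T cells (2 of 10), monocytes (3 of 10), and epithelial cells and fibroblasts (2 of 10), and 15 mitochondrially encoded transcripts, none of which had an entry (0), so that this sign of RNA quality could not be read.

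The gene test was checked on simulated data made from the group means and shuffled residuals of all 12418 genes. Each of the 4 YKL comparisons had 20 runs with 200 changed genes. Residuals were shuffled over all 24 libraries, so the rates hold for an average spread and not for that of each group. Changed genes had a mean log2(FPKM + 1) above 2 with DMSO, so recovery of low genes was not checked. Rescaling here subtracted a median on the log2(FPKM + 1) scale, unlike the division of FPKM used elsewhere. A log2 change of 1 was recovered in 32% of such genes for H929 at 6 h, 29.5% for H929 at 24 h, 33.5% for MM1S at 6 h and 31.5% for MM1S at 24 h on the deposited scale, and in 81%, 82.5%, 84% and 82.5% on the rescaled scale. A log2 change of 2 was recovered in 97% to 98% in these comparisons on both scales. The median number of false calls was 1.5 to 3.5 on the deposited scale and 2.5 to 7.5 on the rescaled scale, with highest values of 135 and 277 in single runs.

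Alternatives were pseudocounts of 0.1 and 5, no filter or a filter at 5 FPKM, median-of-ratios, quantile and ERCC total scaling, a fit of only the groups compared, the replicate number as a block, a constant prior variance, a robust trend, and leaving out each library in turn. Leaving out 3 doubted libraries, on either scale, was added after seeing the data. These were the 2 with widely spread spike-ins and H929 YKL 24 h replicate 2, which had the lowest library scale of its group. Exon lengths for 1 check came from GENCODE by symbol, with no coordinates used. Plots were drawn with Matplotlib 3.10.9 in Python 3.11.15.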

Results

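The series measured how the myeloma lines H929 and MM1S changed their RNA levels under YKL, a CDK7 inhibitor, at 6 h and 24 h. CDK7 is the kinase of TFIIH that phosphorylates RNA polymerase II and activates cell cycle CDKs. Each of the 8 groups held 3 libraries. Of 8 known markers of the lines, 4 differed in the direction of the labels as deposited, among them FGFR3 and MAF. Another 2 (CCR1 and NUAK1) differed in the opposite direction, and 2 were not called. FGFR3, highly expressed in H929, stood at 29.5 ± 1.53 FPKM in H929 and 0.222 ± 0.218 in MM1S with DMSO at 6 h (SD, n = 3). MAF, highly expressed in MM1S, stood at 20.7 ± 2.86 and 45.2 ± 13.2. Markers of T cells, monocytes, and epithelial cells and fibroblasts had 2, 3 and 2 measured members. Among the 4 YKL comparisons, 1 monocyte marker was higher and 1 epithelial or fibroblast marker lower in H929 at 24 h on the deposited scale, and none of the others passed the limma test there.

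Summed gene FPKM differed widely between groups while the spike-ins were level. Divided by summed ERCC FPKM it was 15.9 ± 1.55 with DMSO and 13.8 ± 2.88 with YKL in H929 at 6 h, and 13.5 ± 0.901 and 7.01 ± 2.27 at 24 h (SD, n = 3). In MM1S it was 9.13 ± 1.17 and 7.47 ± 0.688 at 6 h, and 3.87 ± 1.61 and 2.72 ± 0.259 at 24 h. The scale of the median gene was 0.558-fold with YKL in H929 at 24 h and 0.722-fold in MM1S at 6 h. In both cases all 3 YKL libraries lay below all DMSO libraries (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). It was 0.873-fold in H929 at 6 h (exact p = 0.5) and 0.826-fold in MM1S at 24 h (exact p = 0.8), where DMSO libraries spread widely. The DMSO libraries of MM1S themselves fell to 0.437-fold from 6 h to 24 h (exact p = 0.1), while those of H929 stood at 0.945-fold (exact p = 0.7). Genes at or above 1 FPKM numbered 8766 ± 96 to 10741 ± 142 per group. The median log2 change of all genes under YKL was -0.06, -0.46, -0.29 and -0.12 in H929 at 6 h and 24 h and MM1S at 6 h and 24 h as deposited, and 0.07, 0.13, 0.05 and 0.05 after rescaling.

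**Figure D1:**
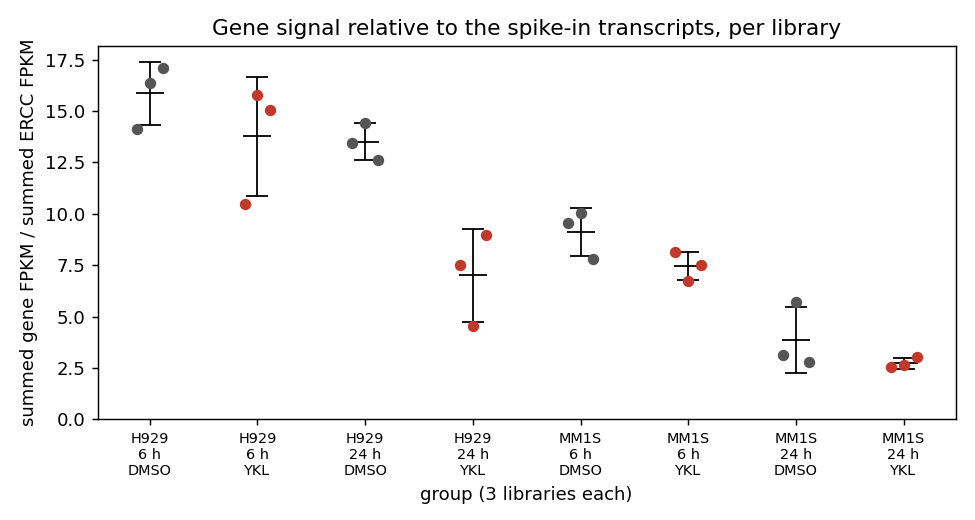
Summed gene FPKM over summed ERCC FPKM, 1 point per library, with the mean and SD of each group of 3 in black. The ratio was 13.5 ± 0.901 with DMSO and 7.01 ± 2.27 with YKL in H929 at 24 h, and 3.87 ± 1.61 and 2.72 ± 0.259 in MM1S at 24 h.

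In H929 at 6 h, a minority of p53 targets rose and a few MYC target genes fell. SESN2 and SESN1, stress-induced regulators of mTORC1, rose from 14.4 ± 2.64 to 42.5 ± 5.33 FPKM and from 4.41 ± 0.251 to 13.6 ± 0.691 FPKM (log2 changes 1.51 ± 0.26 and 1.44 ± 0.27). POLH, a translesion DNA polymerase, rose from 5.23 ± 0.562 to 12.7 ± 2.29 FPKM (SD, n = 3). XBP1, a driver of plasma cell secretion, fell from 3336 ± 531 to 1314 ± 254 FPKM, and ATF4, a regulator of amino acid synthesis, from 782 ± 195 to 331 ± 69.9 FPKM. The chemokine gene CCL3 fell from 337 ± 36.1 to 73.1 ± 18.3 FPKM and CCL4 from 8.99 ± 2.79 to 1.56 ± 2.44 FPKM. Of 27 p53 targets, 6 rose and 0 fell (12 and 0 adjusted over the list alone; 14 rose after rescaling). The list had an adjusted p of 5.09e-09 in limma's camera, and adjusted p = 0.937 with an estimated correlation as deposited and 0.00542 after rescaling. CDKN1A, the p53-induced CDK inhibitor, had a log2 change of 0.94 ± 0.27 (adjusted p = 0.0667 as deposited and 5.39e-05 rescaled, where it rose). Of 44 MYC target and ribosome biogenesis genes, 3 fell (12 adjusted over the list alone, 13 rescaled), namely POLR1B, POLR1C and NOP16, the last from 408 ± 79.3 to 175 ± 42.1 FPKM. The camera test gave this list an adjusted p of 9.09e-11, and p = 0.937 with an estimated correlation (0.00542 rescaled).

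Smaller shifts in H929 at 6 h touched several other lists. TOP2A, the topoisomerase of dividing cells, was the 1 of 44 G2/M genes that fell (4 adjusted over the list alone), from 226 ± 74.1 to 87.1 ± 11 FPKM. GINS3, a replisome subunit, was the 1 of 45 replication genes (1 adjusted over the list alone). STC2, DDIT4 and ATF4 fell and 1 other member rose among 28 ATF4 and amino acid response genes (6 down and 2 up adjusted over the list alone), and STC2 did not pass after rescaling (adjusted p = 0.0539). XBP1 and ATF4 were the 2 of 25 myeloma regulators that fell (3 adjusted over the list alone), and CCR1, a chemokine receptor, and NUAK1 the 2 of 5 MM1S markers (2 adjusted over the list alone). These lists passed camera with adjusted p of 5.37e-05, 0.00147, 0.00386, 0.00319 and 0.00704, each with adjusted p = 0.937 with an estimated correlation. After rescaling that p was 0.0115, 0.111, 0.00542, 0.0115 and 0.0115, with 7, 4, 6, 6 and 2 members down and 0, 1, 1, 2 and 0 up. Cholesterol synthesis (24 genes), ribosomal proteins (50) and cell cycle CDKs (29) also passed camera downward, at adjusted p of 0.0379, 0.0365 and 0.0365, with 0 members called as deposited (0, 0, and 1 up and 1 down adjusted over the list alone) and p = 0.937 with an estimated correlation. Ribosomal protein and cell cycle CDK lists did not pass after rescaling (adjusted p 0.143 and 0.0617).

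The largest changes in H929 at 6 h were single genes of mixed function. ST3GAL4-AS1, an antisense transcript, rose from 4.28 ± 0.936 to 28.3 ± 11.8 FPKM, and MUC20, a mucin, from 0.945 ± 0.774 to 6.60 ± 0.592 FPKM. KRCC1 rose from 2.16 ± 0.353 to 10.8 ± 3.03 FPKM, FAM229A from 3.62 ± 1.78 to 14.3 ± 1.1 FPKM and HIST1H2BG from 3.43 ± 1.37 to 14.1 ± 5.44 FPKM. TEX19, a germ cell gene, fell from 209 ± 34.6 to 30.2 ± 5.26 FPKM, and OR7E12P, an olfactory receptor pseudogene, from 68 ± 12.8 to 13.98 ± 1.67 FPKM. RGS1, a regulator of G protein signalling, fell from 12.4 ± 3.4 to 2.06 ± 1.14 FPKM. CTB-12O2.1 was listed near the floor with DMSO (0.112 ± 0.0147) and at 7.40 ± 4.61 FPKM with YKL, and MYL5 at 5.63 ± 2.93 with DMSO and near the floor with YKL (0.149 ± 0.0168). These 2 genes did not pass after rescaling (adjusted p 0.0548 and 0.0598, limma). Reads of antisense and pseudogene entries may be shared with their partner genes. CDK7 was at 9.47 ± 0.692 FPKM with DMSO and 6.45 ± 1.18 with YKL, and IRF4 at 75.5 ± 9.75 FPKM with DMSO and 55.6 ± 10.4 with YKL. MCL1 was at 720.1 ± 91.4 FPKM with DMSO and 712 ± 141 with YKL, E2F1 at 53.2 ± 8.76 FPKM with DMSO and 37.6 ± 8.75 with YKL and CCND2 at 2.11 ± 0.459 FPKM with DMSO and 1.34 ± 0.468 with YKL. None of these 5 genes passed (adjusted p 0.516, 0.474, 0.984, 0.413 and 0.552, limma). MYC was near the floor in H929 (0.416 ± 0.25 FPKM with DMSO and 0.189 ± 0.0758 with YKL). In all, 128 genes were higher and 144 lower (limma, Benjamini-Hochberg), 79 and 122 of them by at least 1 on the log2 scale, and 635 were higher and 520 lower after rescaling. The count of 272 was 88 or 113 without DMSO replicate 2 or 3, and 165, 134 or 113 without YKL replicate 1, 2 or 3. Without DMSO replicate 1 the split was 69 higher and 167 lower, and without YKL replicate 2 or 3 it was 55 and 79 or 50 and 63. The balance turned without DMSO replicate 2 or 3 (56 higher and 32 lower or 67 and 46) and without YKL replicate 1 (124 and 41).

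In H929 at 24 h, genes of replication, mitosis and ribosome biogenesis fell together. RRM2, a subunit of ribonucleotide reductase, fell from 195 ± 13.2 to 18.01 ± 5.76 FPKM (log2 change -3.41 ± 0.28; SD, n = 3 for FPKM). MCM4, of the replicative helicase, fell from 109 ± 16.6 to 13.4 ± 4.47 FPKM, and CDC45, its partner, from 16.2 ± 2.27 to 1.60 ± 0.417 FPKM. All 45 measured replication genes fell (45 adjusted over the list alone, 42 rescaled). The limma camera test gave this list a Benjamini-Hochberg adjusted p of 1.89e-28, and adjusted p = 0.159 with an estimated correlation (8.52e-06 rescaled). The mitotic kinase AURKB fell from 557 ± 52.3 to 53.1 ± 19.4 FPKM, and the microtubule motor gene KIF2C from 33.8 ± 5.8 to 5.50 ± 0.795 FPKM. CDC20, an activator of the anaphase-promoting complex, fell from 267 ± 30.4 to 37.8 ± 12.9 FPKM. All 44 G2/M genes fell (44 adjusted over the list alone, 37 rescaled), with adjusted p = 0.293 with an estimated correlation (8.52e-06 rescaled). E2F1, the transcription factor of S phase entry, fell from 71.7 ± 4.24 to 9.66 ± 2.82 FPKM.

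Genes of DNA repair and protein synthesis fell in the same libraries. Of 28 homologous recombination genes, 23 fell (24 adjusted over the list alone, 15 rescaled). The checkpoint kinase CHEK1 fell from 37.9 ± 2.75 to 5.42 ± 1.31 FPKM, BRCA1 from 24.4 ± 3.3 to 4.62 ± 1.43 FPKM and FANCG from 42.4 ± 5.38 to 6.46 ± 1.26 FPKM. All 44 MYC target and ribosome biogenesis genes fell (44 adjusted over the list alone, 38 rescaled). The nucleolar gene NPM1 fell from 2106 ± 234 to 411 ± 174 FPKM and NOP56 from 304 ± 11.3 to 73.5 ± 27.6 FPKM. Of 50 ribosomal protein genes, 49 fell (49 adjusted over the list alone, 27 rescaled). RPL5 fell from 3129 ± 497 to 907 ± 336 FPKM, RPL23 from 8446 ± 841 to 2815 ± 846 FPKM and RPS20 from 7996 ± 617 to 2779 ± 1060 FPKM. In the ATF4 list, 22 of 28 fell (24 adjusted over the list alone), and after rescaling 18 fell and 3 rose. PSAT1, of serine synthesis, fell from 89.96 ± 7.35 to 11.6 ± 4.46 FPKM, STC2 from 97.3 ± 8.8 to 12.02 ± 5.11 FPKM and ATF5 from 337 ± 73.5 to 48.1 ± 19.1 FPKM. In the heat shock list, 18 of 21 fell (18 adjusted over the list alone; 14 fell and 1 rose after rescaling). HSPD1 fell from 570.3 ± 115 to 118 ± 44.4 FPKM, FKBP4 from 60.02 ± 4.61 to 15.3 ± 5.95 FPKM and HSP90AA1 from 1229 ± 50.6 to 312 ± 133 FPKM. Cell cycle CDKs and their inhibitors fell in 20 of 29 (21 adjusted over the list alone), and rose in 4 and fell in 10 after rescaling. The adjusted p of these 6 lists with an estimated correlation was 0.371, 0.371, 0.706, 0.522, 0.674 and 0.712 as deposited, and 0.00279, 0.00014, 0.036, 2.67e-05, 0.00229 and 0.0695 rescaled.

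Other lists in H929 at 24 h depended in part on the scale. Genes of oxidative phosphorylation fell in 22 of 37 as deposited (24 adjusted over the list alone), but rose in 5 and fell in 1 after rescaling, where the list did not pass camera (adjusted p = 0.699). The unfolded protein response list fell in 20 of 31 (22 adjusted over the list alone), against 4 up and 11 down rescaled. Glycolysis genes fell in 18 of 29 (19 adjusted over the list alone), against 3 up and 7 down rescaled. These 3 lists passed camera as deposited (adjusted p 0.0467, 0.00449 and 0.0205) and had p = 0.839 each with an estimated correlation. The unfolded protein response and glycolysis lists also passed camera downward after rescaling (adjusted p 0.0407 and 0.0289), with p = 0.0437 and 0.093 with an estimated correlation. Myeloma regulators, the plasma cell surface, NF-kB targets and interferon-stimulated genes passed upward only after rescaling, with 13, 6, 9 and 8 members up, at estimated-correlation p of 0.036, 0.0767, 0.0418 and 0.0813. The p53 list, raised at 6 h, had 3 of 27 genes up and 8 down (3 and 8 adjusted over the list alone; 11 up and 4 down rescaled) and did not pass camera (adjusted p = 0.386). IRF4 and MCL1 had log2 changes of -0.24 and -0.10 as deposited (adjusted p 0.515 and 0.798), and rose by 0.58 and 0.74 after rescaling.

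Several histone genes rose in H929 at 24 h, as did 3 of 13 Y, vault and SNAR RNAs, a family counted after its values were seen. HIST1H2BK rose from 50.9 ± 2.06 to 363 ± 71.3 FPKM, HIST2H2BE from 3.28 ± 1.44 to 81.1 ± 33.6 FPKM and HIST1H2BG from 2.03 ± 1.05 to 36.1 ± 14.3 FPKM. HIST1H4C fell from 714 ± 186 to 56.3 ± 0.753 FPKM. Of 20 replication-dependent histone genes, 8 rose and 3 fell (8 and 3 adjusted over the list alone, 9 and 3 rescaled), with an adjusted p of 8.3e-11 in camera and 0.0112 with an estimated correlation. Histone genes are near-identical copies, so reads may be split between members. RNY5, a Y RNA, was listed at the floor in DMSO (0.110 ± 0.000125) and at 1660 ± 839 FPKM with YKL. VTRNA1-3, a vault RNA, was at 0.110 ± 0.00137 and 143 ± 98, and SNAR-A11 at 0.111 ± 0.00121 and 28.2 ± 2.78. Division by length makes FPKM large for such short genes, so these levels were not compared with those of other genes. MILR1, an immunoreceptor gene, rose from 1.13 ± 0.756 to 25.3 ± 12.9 FPKM. MT2A, a metallothionein, fell from 130.3 ± 10.7 to 9.76 ± 1.1 FPKM, TEX19 from 199.7 ± 28.9 to 15.9 ± 4.27 FPKM and SNHG1, a host gene of small nucleolar RNAs, from 479.5 ± 92.9 to 45.4 ± 17.3 FPKM. XBP1 fell from 3002 ± 294 to 1433 ± 492 FPKM as deposited and had a rescaled adjusted p of 0.0539. CDK7 was at 7.33 ± 2.3 FPKM with DMSO and 4.06 ± 1.37 with YKL, CDKN1A at 86.7 ± 15.5 FPKM with DMSO and 56.97 ± 18.4 with YKL and CCND2 at 2.06 ± 0.269 FPKM with DMSO and 1.58 ± 0.618 with YKL. These genes did not pass (adjusted p 0.0838, 0.0676 and 0.492, limma). MYC stayed near the floor (0.517 ± 0.197 FPKM with DMSO and 0.299 ± 0.282 with YKL, adjusted p 0.612). In all, 332 genes were higher and 4396 lower (limma), 158 and 2470 of them by at least 1 on the log2 scale, against 2585 higher and 1550 lower after rescaling. The count of 4728 was 2844 without YKL replicate 2 and 2846 without the 3 doubted libraries.

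In MM1S at 6 h, most measured replication and heat shock genes fell. MCM4 fell from 57.8 ± 6.11 to 14.3 ± 1.35 FPKM (log2 change -1.94 ± 0.26; SD, n = 3 for FPKM). PCNA, the sliding clamp of DNA replication, fell from 138 ± 28.6 to 32.6 ± 8.05 FPKM and GINS3 from 8.10 ± 0.697 to 1.80 ± 0.566 FPKM. Of 45 replication genes, 30 fell (36 adjusted over the list alone, 28 rescaled). The heat shock genes HSPA1B, DNAJB1 and CHORDC1 fell from 33.6 ± 5.51 to 7.99 ± 0.574 FPKM, 289 ± 23.1 to 52.9 ± 5.97 FPKM and 9.50 ± 0.413 to 1.96 ± 1.06 FPKM. In that list 12 of 21 fell (16 adjusted over the list alone; 12 fell and 2 rose rescaled). Of 44 MYC target and ribosome biogenesis genes, 21 fell (33 adjusted over the list alone, 19 rescaled). NCL, which encodes nucleolin, fell from 414 ± 17.1 to 161 ± 10 FPKM, GNL3 from 12.1 ± 2.41 to 4.26 ± 0.958 FPKM and GAR1 from 78.8 ± 4.1 to 31.9 ± 5.71 FPKM. These 3 lists had camera p of 3.12e-16, 7.69e-07 and 4.12e-10, estimated-correlation p of 0.875, 0.875 and 0.91 as deposited, and 0.000547, 0.00162 and 0.00763 rescaled.

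Further cell cycle and repair genes fell in MM1S at 6 h. CDC25A, a phosphatase that activates CDKs, fell from 19.3 ± 1.74 to 5.68 ± 0.958 FPKM, CCNE1, which encodes cyclin E, from 21.1 ± 5.45 to 8.15 ± 2.08 FPKM and CDK1 from 63.9 ± 2.69 to 27.8 ± 3.23 FPKM. CHEK1, BRCA1 and FANCL fell from 9.99 ± 2 to 3.96 ± 0.463 FPKM, 15.1 ± 0.489 to 6.36 ± 0.0965 FPKM and 14.6 ± 1.45 to 4.79 ± 0.819 FPKM, the last not past the test after rescaling (adjusted p = 0.0512, limma). Counts of fallen genes were 9 of 29 cell cycle CDKs (13 adjusted over the list alone), 10 of 28 homologous recombination genes (12), and 8 of 44 G2/M genes (12), the last with SPC25, TOP2A and MELK. DDIT4, PSAT1 and MTHFD2 were among 6 of 28 ATF4 list genes that fell (11 adjusted over the list alone). Immediate early genes fell in 9 of 23 (9) and myeloma regulators in 7 of 25 (9), where brackets give genes adjusted over the list alone. These 6 lists passed camera (adjusted p 0.0108, 0.00184, 0.00129, 0.0132, 0.0339 and 0.0339), each with p = 0.91 with an estimated correlation. After rescaling 7, 7, 6, 4, 5 and 3 of their members fell and 1, 0, 2, 1, 2 and 3 rose. Only the ATF4 list then passed with an estimated correlation (0.0244; others 0.154, 0.115, 0.115, 0.084 and 0.154). HIST1H2BK rose from 8.90 ± 0.583 to 16.03 ± 2.27 FPKM, and HIST1H4B stood near the floor with DMSO (0.103 ± 0.0188) and at 2.27 ± 1.34 with YKL. They were the 2 histone genes up, with 1 down, of 20 (2 and 1 adjusted over the list alone, 3 and 0 rescaled; camera p = 0.0243, and 0.875 with an estimated correlation), and after rescaling the list did not pass camera (adjusted p = 0.322). After rescaling, ribosomal protein and oxidative phosphorylation genes passed upward with 7 of 50 and 9 of 37 members (estimated-correlation p 0.203 and 0.154), where 0 and 0 rose as deposited.

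Single genes with the largest changes in MM1S at 6 h were again varied. RNASEK rose from 5.01 ± 4.29 to 39.4 ± 29.1 FPKM, CEACAM21, a cell adhesion gene, from 6.65 ± 2.7 to 35.04 ± 2.07 FPKM, and SCG5 from 1.66 ± 0.623 to 8.39 ± 2.58 FPKM. LAMB2P1 rose from 1.75 ± 0.0344 to 9.12 ± 4.65 FPKM, SNAI3-AS1 from 2.06 ± 1.52 to 8.89 ± 2 FPKM and HOXB-AS3 from 0.398 ± 0.499 to 3.59 ± 1.65 FPKM. ANKRD37, a hypoxia-induced gene, fell from 45.8 ± 6.23 to 3.31 ± 2.54 FPKM, and SNHG12 from 73.1 ± 12.7 to 8.33 ± 2.67 FPKM. FUBP1, a single-strand DNA binding regulator of MYC, fell from 53.3 ± 4.66 to 6.32 ± 0.23 FPKM, and SRSF3, a splicing factor, from 89.3 ± 7.78 to 12.8 ± 1.05 FPKM. LSM6 fell from 50.1 ± 13.9 to 7.54 ± 4.23 FPKM. As deposited MYC fell from 34.7 ± 13.9 to 14.4 ± 4.91 FPKM (adjusted p = 0.0273, rescaled 0.0543). CCND2, which encodes cyclin D2, fell from 79.6 ± 6.3 to 39.03 ± 2.31 FPKM (adjusted p = 0.0297, rescaled 0.153). E2F1 fell on both scales, from 21.5 ± 1.07 to 10.6 ± 2.26 FPKM. MCL1, an anti-apoptotic gene, had a log2 change of 0.30 ± 0.26 (adjusted p = 0.492) and rose by 0.77 after rescaling. The genes CDK7, IRF4, CDKN1A and XBP1 did not pass (adjusted p 0.682, 0.511, 0.794 and 0.283). In all, 115 genes were higher and 1245 lower (limma), 52 and 670 of them by at least 1 on the log2 scale, against 1024 and 895 after rescaling. The count of 1360 was 536 or 672 without DMSO replicate 1 or 2, and 674 or 573 without YKL replicate 2 or 3. Without DMSO replicate 3 it was 72 higher and 844 lower.

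In MM1S at 24 h, most measured replication and mitosis genes fell. RRM2 fell from 56.9 ± 27.5 to 5.09 ± 1.42 FPKM (log2 change -3.17 ± 0.28; SD, n = 3 for FPKM). MCM2 fell from 24.5 ± 12.8 to 1.97 ± 0.526 FPKM, MCM3 from 38.4 ± 15.4 to 3.74 ± 1.05 FPKM, MCM4 from 17.6 ± 6.14 to 1.98 ± 0.605 FPKM and TYMS, which encodes thymidylate synthase, from 60.8 ± 21.7 to 6.26 ± 1.85 FPKM. Of 45 replication genes, 38 fell (43 adjusted over the list alone, 43 rescaled), at camera p = 2.66e-54 and p = 0.0338 with an estimated correlation. In the G2/M list, 37 of 44 fell (43 adjusted over the list alone, 42 rescaled). AURKB fell from 90.95 ± 46.5 to 14.7 ± 4.06 FPKM, SPC25 from 5.80 ± 2.25 to 0.716 ± 0.296 FPKM and MELK from 12.2 ± 7.32 to 0.902 ± 0.157 FPKM. The estimated-correlation p of that list was 0.0921 as deposited and 1.2e-06 rescaled. E2F1 fell from 12.7 ± 6.4 to 1.09 ± 0.417 FPKM, CDC25A from 9.35 ± 2.54 to 1.23 ± 0.332 FPKM and CDK2 from 35.2 ± 19.1 to 5.60 ± 0.571 FPKM. They were part of 13 of 29 cell cycle CDK genes that fell (15 adjusted over the list alone; 16 fell and 1 rose rescaled). UBE2T, FANCG and FANCL of the Fanconi pathway fell from 46 ± 18.5 to 7.09 ± 1.78 FPKM, 15.5 ± 7.79 to 3.05 ± 0.493 FPKM and 6.64 ± 3.69 to 0.948 ± 0.796 FPKM. In that list 17 of 28 fell (20 adjusted over the list alone; 21 fell and 1 rose rescaled).

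Genes of serine synthesis and glycolysis were also among those that fell in MM1S at 24 h. PSAT1 and PHGDH, both of serine synthesis, fell from 17.6 ± 6.35 to 2.07 ± 0.153 FPKM and 4.03 ± 1.81 to 0.642 ± 0.235 FPKM, and AARS, an aminoacyl-tRNA synthetase gene, from 9.24 ± 3.69 to 2.24 ± 0.206 FPKM. In the ATF4 list 14 of 28 fell (18 adjusted over the list alone, 20 rescaled). LDHA, which encodes lactate dehydrogenase, fell from 89.7 ± 32.9 to 23.2 ± 6.58 FPKM, ENO2 from 30.2 ± 10.4 to 9.54 ± 1.96 FPKM and PKM from 41.6 ± 14.6 to 15.8 ± 3.58 FPKM. In all, 13 of 29 glycolysis genes fell (17 adjusted over the list alone, 18 rescaled). ODC1, the first enzyme of polyamine synthesis, and PAICS, of purine synthesis, fell from 94.8 ± 38.6 to 30.6 ± 5.6 FPKM and 13.9 ± 4.23 to 5.59 ± 1.44 FPKM. They were among 9 of 44 MYC target genes that fell (13 adjusted over the list alone, 14 rescaled). Ribosomal protein genes fell in 4 of 50 as deposited (22 adjusted over the list alone, 26 rescaled). RPL23 fell from 3032 ± 1230 to 1126 ± 86 FPKM, RPS20 from 2416 ± 781 to 1016 ± 154 FPKM and RPS25 from 2252 ± 774 to 1159 ± 130 FPKM. Cholesterol synthesis genes fell in 4 of 24, heat shock genes in 3 of 21 and oxidative phosphorylation genes in 2 of 37 (4, 6 and 1 adjusted over the list alone; 7, 8 and 10 fell and 1 rose in each rescaled). With an estimated correlation, cell cycle CDK, homologous recombination, ATF4, glycolysis, MYC target, ribosomal protein, cholesterol, heat shock and oxidative phosphorylation lists had p = 0.282, 0.248, 0.27, 0.483, 0.605, 0.605, 0.605, 0.605 and 0.605. After rescaling those p were 0.00612, 0.00146, 2.43e-06, 0.00212, 0.0469, 0.0469, 0.0197, 0.0689 and 0.0689.

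Some histone genes rose in MM1S at 24 h too, HIST1H2BK from 4.04 ± 0.646 to 36.1 ± 2.19 FPKM, HIST1H2BD from 4.47 ± 3.14 to 23.4 ± 5.06 FPKM and HIST2H2BE from 0.722 ± 0.158 to 6.55 ± 1.56 FPKM. Of 20 histone genes 4 rose and 2 fell (5 and 3 adjusted over the list alone, 6 and 3 rescaled; camera p = 0.00168, and 0.254 with an estimated correlation), and after rescaling the list did not pass camera (adjusted p = 0.0994). PARD3-AS1 rose from 5.34 ± 5.07 to 27.4 ± 3.78 FPKM and C11orf96 from 59.9 ± 33.5 to 269 ± 23.5 FPKM. SCO2, a copper chaperone gene, stood near the floor in DMSO (0.0844 ± 0.0319) and at 9.69 ± 2.26 with YKL. FAM111B fell from 18.9 ± 7.25 to 1.37 ± 0.526 FPKM and SNAR-G1, a short RNA, from 135 ± 66.3 to 12.4 ± 12.1 FPKM. Several lists passed camera upward with few or no called members as deposited: p53 targets (0 up, 0 adjusted over the list alone), NF-kB targets (0, 0), BCL2 and IAP families (0, 1), interferon-stimulated genes (0, 0), myeloma regulators (1, 1), immediate early genes (1, 2) and MM1S markers (1, 1). In the same order 0, 0, 2, 0, 2, 3 and 0 members fell. Their p with an estimated correlation was 0.62, 0.605, 0.605, 0.62, 0.634, 0.605 and 0.605. After rescaling 9, 8, 8, 5, 11, 6 and 3 of their members rose and 1, 1, 2, 0, 3, 4 and 0 fell, and that p was 0.104, 0.0121, 0.0229, 0.0659, 0.0229, 0.0469 and 0.0469. The plasma cell surface list and the list of CDK7, TFIIH and transcription kinases did not pass as deposited (adjusted p 0.0624 and 0.0594) and had 8 and 7 members up after rescaling.

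Of the genes named in every comparison, CCND2 fell in MM1S at 24 h, from 57.2 ± 29 to 26.4 ± 6.59 FPKM, on both scales. MCL1 stood at 134 ± 56.5 FPKM with DMSO and 226 ± 20 with YKL (adjusted p = 0.0545), and XBP1 at 532 ± 296 FPKM with DMSO and 702 ± 138 with YKL (0.406). Both rose after rescaling, by 1.11 and 0.79. CDKN1A had a log2 change of -0.69 ± 0.27 (adjusted p = 0.145) and fell after rescaling (0.014). The genes CDK7, MYC and IRF4 did not pass (adjusted p 0.428, 0.757 and 0.999). In all, 85 genes were higher and 841 lower (limma), 50 and 641 of them by at least 1 on the log2 scale, against 1792 and 1655 after rescaling. The count of 926 was 1861 without DMSO replicate 3, and 491 or 579 without YKL replicate 1 or 2. Without DMSO replicate 2 the split was 305 higher and 424 lower and the median log2 change of all genes was 0.03, so that the excess of lower genes rests largely on 1 DMSO library. Without DMSO replicate 1 or YKL replicate 3 it was 35 and 686 or 43 and 600.

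**Figure D2:**
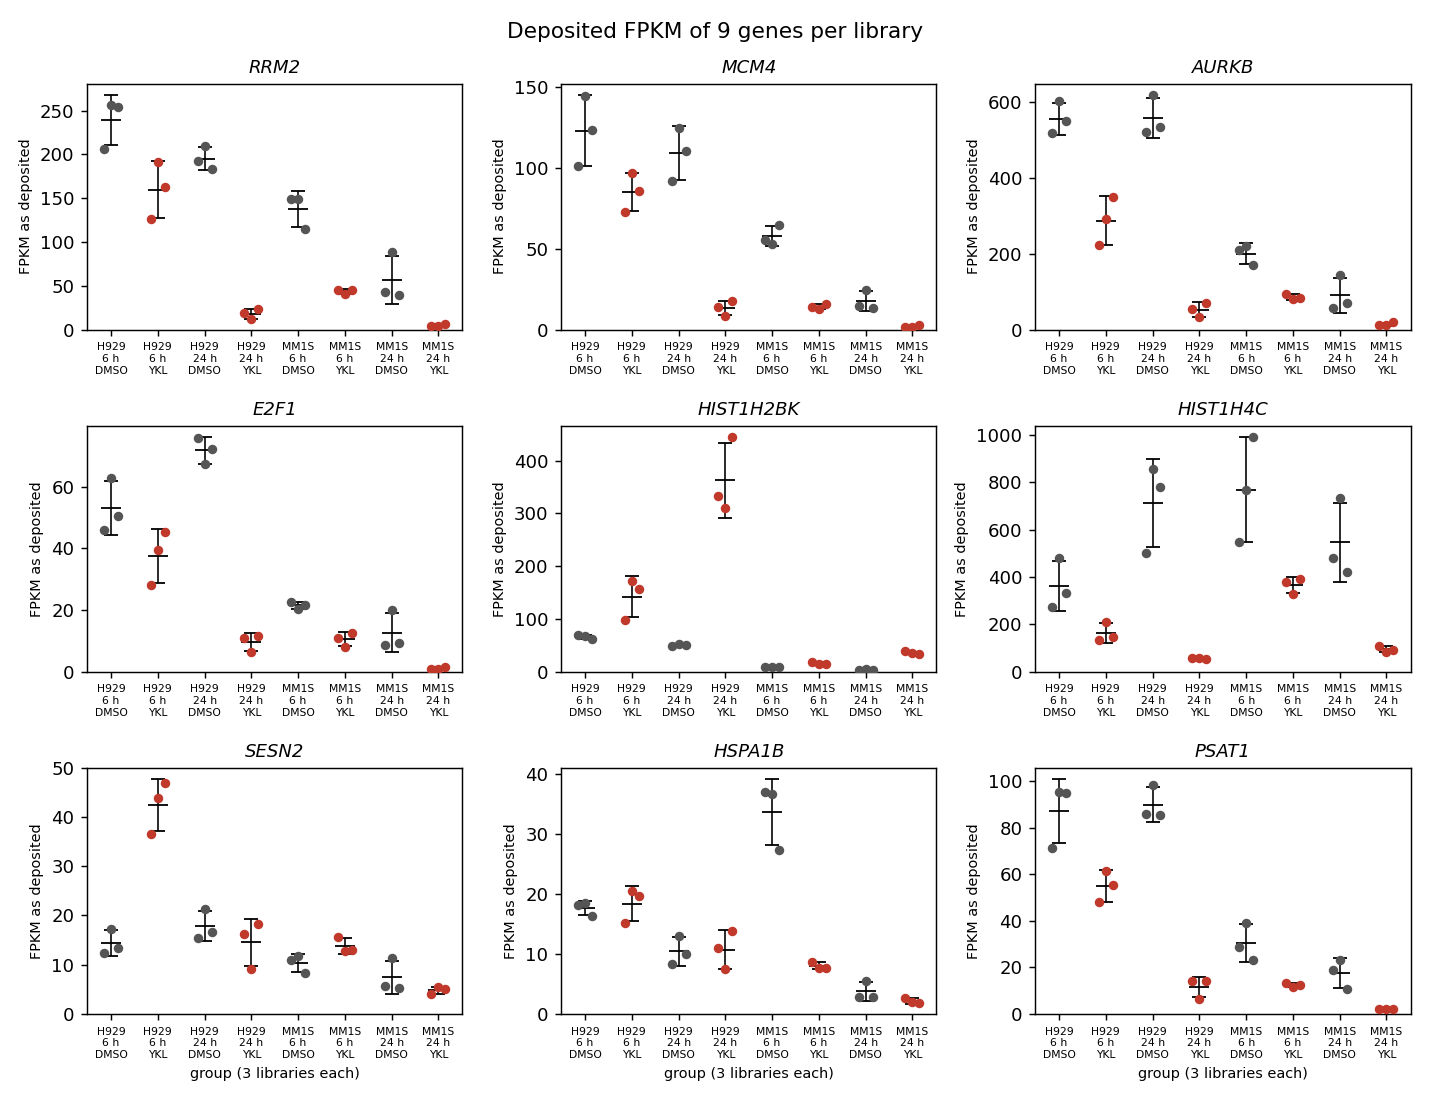
Deposited FPKM of 9 genes from the rule for named genes, 1 point per library (grey, DMSO; red, YKL), with the mean and SD of each group of 3 in black. RRM2 with YKL at 24 h was 18.01 ± 5.76 in H929 and 5.09 ± 1.42 in MM1S, against 195 ± 13.2 and 56.9 ± 27.5 with DMSO.

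**Figure D3:**
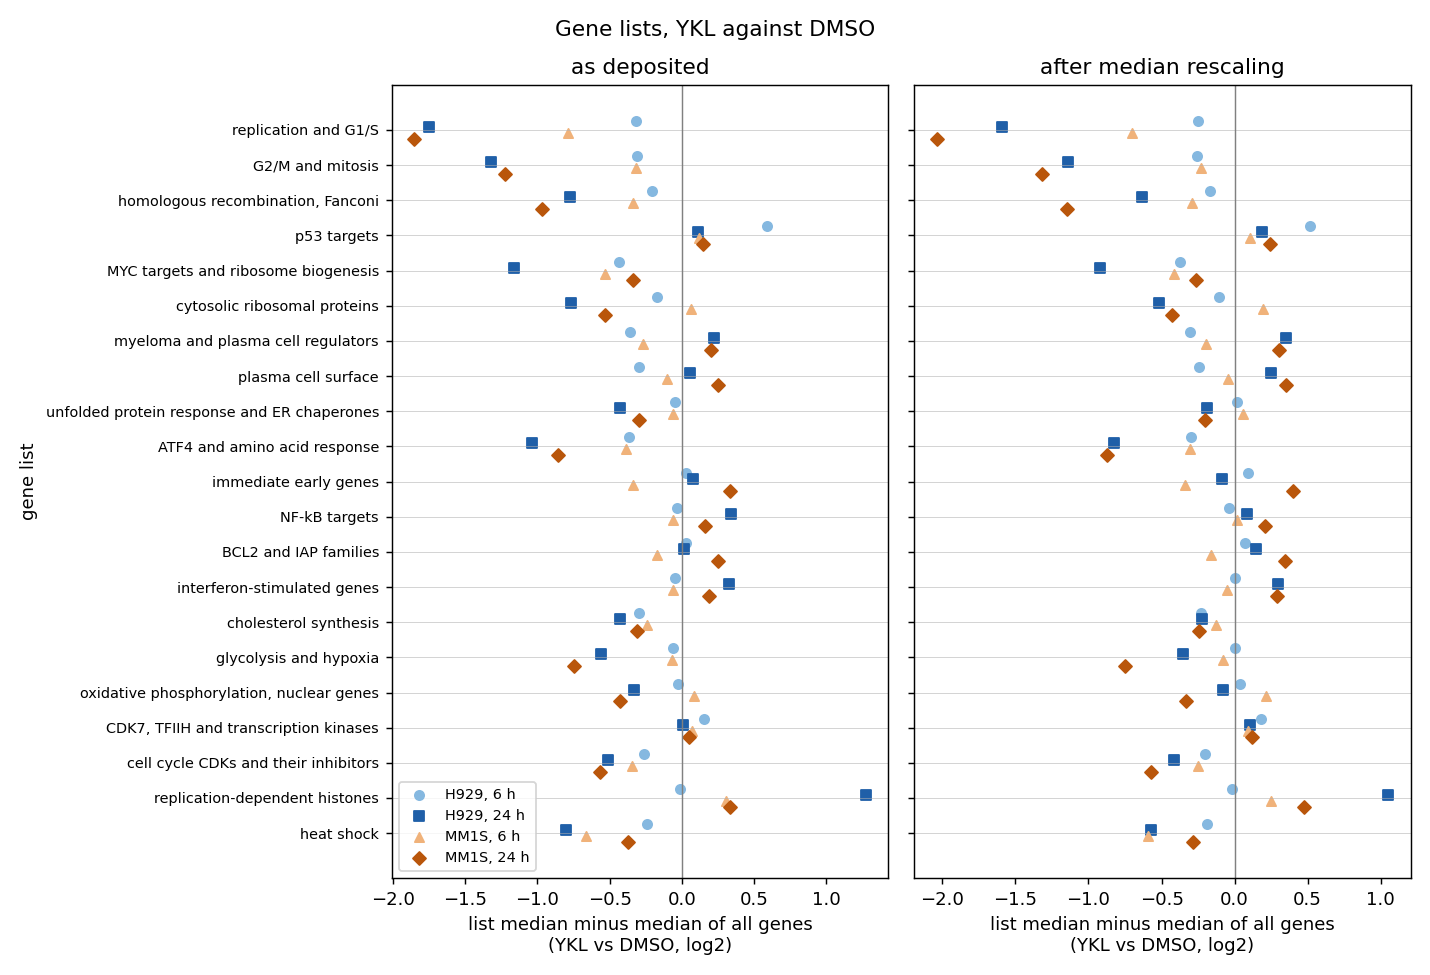
Median log2 change of each gene list under YKL minus the median of all genes, as deposited (left) and after rescaling (right), 1 symbol per line and time. The replication list lay at -1.75 in H929 and -1.85 in MM1S at 24 h as deposited, and at -1.59 and -2.04 rescaled, while the oxidative phosphorylation list lay at -0.33 and -0.08 in H929 at 24 h.

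The responses of both lines shared genes beyond the number of independent lists. At 6 h, 13 genes were higher and 101 lower in both lines, against 1.19 and 14.4 for independent lists, and after rescaling 239 and 287, against 52.4 and 37.5. At 24 h, 29 were higher and 684 lower in both, against 2.27 and 298, and 945 and 773 rescaled, against 373 and 207. Within H929, 45 genes were higher and 126 lower at both times, against 3.42 and 51.0, and within MM1S 14 and 326, against 0.787 and 84.3. After rescaling they were 423 and 311 in H929, against 132 and 64.9, and 476 and 415 in MM1S, against 148 and 119. Across genes, which are not independent replicates, Pearson's r of the log2 changes between lines was 0.452 at 6 h and 0.506 at 24 h, and Spearman's rho was 0.475 and 0.484. Between times it was 0.481 in H929 and 0.409 in MM1S (rho 0.537 and 0.422). The pairs of comparisons shared no libraries.

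The response differed between lines in 21 genes at 6 h and 169 at 24 h by the interaction test, with the labelled dose differing too. At 6 h, KRCC1, FAM89A and PDCL3 changed more upward in H929 and GUCA1C and CMTM2 more upward in MM1S. The replication, p53 and heat shock lists lay higher in H929 (list medians 0.48, 0.47 and 0.41 above all genes), with 0, 1 and 1 called members and 6, 9 and 8 adjusted over the list alone. Their adjusted p was 2e-08, 2.49e-07 and 0.000503 in camera, 0.975 with an estimated correlation, and 0.00333, 0.0185 and 0.0185 with an estimated correlation after rescaling. At 24 h, RNY5, SNAR-A11 and MILR1 changed more upward in H929, and OR7E12P, STC2 and ATF5 more downward. STC2 and ATF5 changed by -3.00 and -2.84 in H929, nearly the whole of their differences of -3.01 and -2.91. The MYC target list lay lower in H929 (-0.79, with 2 called members and 35 adjusted over the list alone; camera p = 5.85e-12, p = 0.97 with an estimated correlation and 0.0102 rescaled). Histone genes (0.79, with 2 up) and heat shock genes (-0.47, with 1 down) also passed camera, with p = 0.157 and 0.97 with an estimated correlation, and 3 up and 2 down and 7 down adjusted over the list alone. Higher and lower genes numbered 17 and 4 at 6 h (90 and 51 rescaled), and 36 and 133 at 24 h (999 and 537 rescaled). Leaving out H929 DMSO replicate 1, 2 or 3 gave 9, 9 or 7 genes at 6 h, and H929 YKL 1, 2 or 3 gave 72, 0 or 4 (945 genes at an unadjusted p under 0.05 in limma beside the 0). Leaving out MM1S DMSO 1, 2 or 3 gave 0, 10 or 4 (1016 genes at an unadjusted p under 0.05 in limma beside the 0), and MM1S YKL 3 gave 5. At 24 h H929 DMSO 1, 2 or 3 gave 108, 50 or 79, H929 YKL 3 gave 651, MM1S DMSO 1 or 2 gave 79 or 2396, and MM1S YKL 1, 2 or 3 gave 89, 69 or 61. Without H929 YKL 2 or MM1S DMSO 3 the excess of lower genes was gone, at 57 higher and 58 lower or 56 and 58, and without H929 YKL 1 it was 23 and 116.

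The response changed with time in 803 genes of H929, 36 more upward and 767 more downward at 24 h than at 6 h (716 and 579 rescaled), and in 10 genes of MM1S, 4 and 6 (534 and 780 rescaled). RRM2 fell more at 24 h than at 6 h in H929 (difference -2.82), as did MT2A (-3.26). Of 45 replication genes 39 changed more downward (42 adjusted over the list alone, 34 rescaled, camera p = 4.67e-34, p = 0.0922 with an estimated correlation). The p53 list lay lower at 24 h than at 6 h in H929, with 10 of 27 down (15 adjusted over the list alone; 4 up and 8 down rescaled; camera p = 0.00118, p = 0.596 with an estimated correlation and 0.0888 rescaled). In MM1S, DUSP5, HIST1H2BK and CHORDC1 changed more upward and SCG5, CENPM and PHF10 more downward at 24 h. Its replication and G2/M lists lay lower (-0.86 and -0.94), with 1 and 0 called members and 15 and 9 adjusted over the list alone (camera p 5.72e-24 and 1.57e-24, p = 0.262 each with an estimated correlation, 1.19e-05 and 3.7e-06 rescaled). The H929 count was 328 or 525 without DMSO 6 h replicate 1 or 3, 1418, 296 or 292 without YKL 6 h replicate 1, 2 or 3. It was 273 or 494 without DMSO 24 h replicate 2 or 3, and 332 or 1450 without YKL 24 h replicate 2 or 3. Without YKL 24 h replicate 1 the split was 18 more upward and 650 more downward. The MM1S count was 3 or 6 without DMSO 6 h replicate 2 or 3, 16 or 1 without YKL 6 h replicate 1 or 2. It was 5, 323 or 74 without DMSO 24 h replicate 1, 2 or 3, and 1 without YKL 24 h replicate 1 or 2.

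With DMSO at 6 h, 4519 genes were higher and 1573 lower in H929 than in MM1S (limma; 2805 and 3854 rescaled). HCST and MLC1 stood at 538 ± 54.2 and 592 ± 105 FPKM in H929 and 0.426 ± 0.298 and 0.560 ± 0.349 in MM1S, and SNAR-I at 499 ± 115 and near the floor (0.0935 ± 0.00765). PCP4, LAPTM5 and CD74, the invariant chain, were higher in MM1S, at 704 ± 162, 809 ± 90.2 and 456 ± 52.6, against 2.07 ± 3.33, 3.52 ± 2.36 and 1.57 ± 1.04 in H929. Of the H929 markers, WHSC1 and FGFR3 were higher in H929 and LETM1 was not called (adjusted p = 0.882; lower in H929 after rescaling). Of the MM1S markers, MAF and CX3CR1 were higher in MM1S, CCR1 and NUAK1 higher in H929, and ITGB7 not called (0.745; lower in H929 after rescaling). NF-kB targets lay lower in H929, with 11 of 21 down and 6 up (11 and 6 adjusted over the list alone; camera p = 0.00154, p = 0.882 with an estimated correlation and 0.0189 rescaled). MYC stood at 0.416 ± 0.25 in H929 and 34.7 ± 13.9 in MM1S with DMSO at 6 h, as a level from the list of genes named in every comparison.

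Among DMSO libraries, 13 genes were higher and 5 lower at 24 h than at 6 h in H929 (80 and 47 rescaled). MGAT3-AS1, PPP4R2 and NKX2-5 rose, the second from 2.17 ± 0.339 to 9.72 ± 2.04, and RGS1, BHLHE40 and HES1 fell, RGS1 from 12.4 ± 3.4 to 1.13 ± 0.756. Glycolysis genes lay lower, with 1 of 29 down (3 adjusted over the list alone; camera p = 8.64e-08, p = 0.976 with an estimated correlation and 0.000577 rescaled). In MM1S, 32 genes were higher and 6950 lower at 24 h, against 1274 and 669 after rescaling, and 130 genes were called in opposite directions by the 2 scales. PFKFB4, of glycolysis, rose from 1.56 ± 0.669 to 7.25 ± 3.04 and CDKN1C, a CDK inhibitor, from 15.8 ± 3.53 to 47.4 ± 21, with MCTS2P also up. NTAN1, FAM166A and SNAR-C3 fell, the last from 27.5 ± 30 to near the floor (0.0598 ± 0.0202) and not past the test after rescaling (adjusted p = 0.188, limma). Heat shock genes fell in 19 of 21 (19 adjusted over the list alone; camera p = 6.99e-06, p = 0.917 with an estimated correlation), and 11 fell and 1 rose after rescaling (0.00134). The H929 count of 18 was 9 without 6 h replicate 1 and 10 without 24 h replicate 1 or 3, and the MM1S count of 6982 was 4560 without 24 h replicate 3. The number of higher genes there was 67 without 6 h replicate 3 and 18 without 24 h replicate 1.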

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

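The tests of library scale, of summed histone levels and of other splits of the samples were chosen after the results they bear on had been seen. The gene and list values of the next 3 paragraphs come from tests of a difference between lines or between times. There, positive values mean a more upward change in H929 than in MM1S, or at 24 h than at 6 h, in log2(FPKM + 1). A positive value can come from a smaller fall, or from DMSO levels that differ, and need not be a rise under YKL.

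Between the lines at 6 h 21 genes differed, with values of 2.36 for KRCC1, 2.24 for FAM89A, 2.18 for PDCL3, 1.98 for HSPA1B, and -2.07 for CMTM2 and -2.13 for GUCA1C. All 6 also passed after rescaling. List medians less that of all genes were 0.48 for replication and G1/S, 0.47 for p53 targets and 0.41 for heat shock, all higher in H929. At 24 h 169 genes differed, with 10.4 for RNY5, 4.72 for SNAR-A11, 3.59 for MILR1, 2.70 for HIST1H2BG, 2.103 for HIST2H2BE. Negative values were -1.21 for CHEK1, -2.07 for C11orf96, -2.27 for TEX19, -2.91 for ATF5, -3.01 for STC2 and -3.34 for OR7E12P, of which 10 of 11 also passed after rescaling. The difference of RNY5 and SNAR-A11 rests on DMSO and MM1S libraries at the floor, so it is no fold. SNAR-A11 was also listed at 63.7 FPKM in 1 of 3 H929 YKL libraries at 6 h and near 0.1 in the others, and SCO2, named for MM1S at 24 h, at 29.7, 0.138 and 2.97 FPKM in the H929 DMSO libraries at 24 h. The MYC target list lay at -0.79.

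Between the times in H929 803 genes differed. Positive values were 10.4 for RNY5, 7.04 for VTRNA1-3, 3.33 for MYL5, 2.94 for HIST2H2BE, 2.42 for MILR1, 2.14 for RGS1, 1.86 for HIST1H2BG and 1.74 for HIST1H2BK. The values of RGS1 and MYL5 rest on their falls at 6 h. RGS1 had a log2 change of -2.16 under YKL at 6 h, and its DMSO level was itself lower at 24 h. MYL5 was near the floor with YKL at 6 h (0.149 ± 0.0168 FPKM). RNY5 with YKL at 24 h was listed at 1630, 834 and 2510 FPKM in the 3 libraries. VTRNA1-3 was also listed at 189 FPKM in 1 DMSO library and 118 in 1 YKL library at 6 h. Growth and cell cycle genes had negative values: NOP56 -1.32, RPS20 -1.43, RPL23 -1.43, RPL5 -1.64, NPM1 -1.97, KIF2C -1.83, CDC20 -2.17, E2F1 -2.30, MCM4 -2.45, AURKB -2.46, CDC45 -2.72 and RRM2 -2.82. So had repair genes (CHEK1 -1.59, POLH -1.63, BRCA1 -1.67, FANCG -2.06), p53 targets (CDKN1A -1.58, SESN1 -1.76, SESN2 -1.82), chaperones (HSP90AA1 -1.50, FKBP4 -1.66, HSPD1 -2.06) and ATF4 list genes (STC2 -1.73, ATF5 -1.82, PSAT1 -2.28). The remaining values were -1.19 for MUC20, -1.69 for SNHG1, -2.48 for HIST1H4C, -2.82 for CTB-12O2.1 and -3.26 for MT2A. Of the 38 genes, 35 passed after rescaling.

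Of the lists that differed between the times in H929, higher ones lay at 1.73 for replication-dependent histones, 0.67 for MM1S markers, 0.64 for myeloma regulators, 0.49 for NF-kB targets and 0.24 for the plasma cell surface. Lower lists lay at -0.36 for the unfolded protein response, -0.45 for heat shock, -0.59 for ribosomal proteins, -0.61 for MYC targets, -0.68 for the ATF4 list, -0.87 for homologous recombination, -0.92 for G2/M and -1.38 for replication. Between the times in MM1S 10 genes differed, with 2.47 for DUSP5, 2.11 for HIST1H2BK, 1.76 for CHORDC1, -2.06 for PHF10, -2.20 for CENPM and -2.34 for SCG5. Lists there lay at 0.60 for MM1S markers, 0.57 for NF-kB targets, 0.57 for myeloma regulators, 0.49 for BCL2 and IAP families, 0.47 for immediate early genes, 0.30 for the plasma cell surface, and 0.23 for heat shock. The heat shock value rests in part on the controls, since with DMSO alone most heat shock genes of MM1S fell over time. HSPA1B was at 36.98, 36.6 and 27.26 FPKM with DMSO at 6 h and 2.853, 5.515 and 2.827 at 24 h. With YKL it fell too, from 8.655, 7.614 and 7.714 FPKM to 2.671, 1.97 and 1.835. Lower lists lay at -0.40 for cell cycle CDKs, -0.44 for oxidative phosphorylation, -0.44 for the ATF4 list, -0.45 for glycolysis, -0.51 for homologous recombination, -0.62 for ribosomal proteins, -0.86 for replication and -0.94 for G2/M. All these lists passed camera as deposited. With an estimated correlation as deposited only the histone list between times in H929 kept its call (adjusted p = 0.00377, limma). The others had limma adjusted p = 0.975 between lines at 6 h, 0.97 at 24 h, 0.0922 to 0.74 between times in H929 and 0.262 to 0.583 in MM1S. That all passed with an estimated correlation after rescaling was the rule by which they were chosen, so it is no further test. Left out by this rule were 6 lists that passed camera as deposited. Between lines these were ribosomal proteins at 6 h (-0.23; p = 0.116 with an estimated correlation after rescaling) and histones (0.79; 0.0829) and heat shock (-0.47; 0.0557) at 24 h. Between times they were p53 targets (-0.45; 0.0888) and cell cycle CDKs (-0.41; 0.0814) in H929 and MYC targets (0.24; 0.452) in MM1S (limma).

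Most genes of H929 lay lower against the spike-ins with YKL at 24 h. A single library as the source is argued against, since without YKL replicate 2 the difference in log2 library scale was -0.57 and both other YKL libraries lay below all DMSO libraries. Differences in culture or input unrelated to the compound cannot be told apart from it: the DMSO libraries of MM1S differed between the times by -1.19 with no compound, while those of H929 differed by -0.08. A lower RNA content under the compound in both lines stays open as well, and it may account for H929 alone. MM1S had -0.28 at 24 h with overlapping libraries, and -0.47 at 6 h with all 3 YKL libraries below all DMSO libraries. H929 at 6 h had -0.20 with overlapping libraries.

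Summed over all 20 entries, H2B histone levels rose at 24 h in both lines while the summed 14 H4 entries fell. The fall of the H4 sum follows HIST1H4C, the only 1 of 7 tested H4 genes called lower as deposited in each line, and the median H4 gene changed by 0.45 in H929 and -0.43 in MM1S (0.547 and -0.457 rescaled). The H2B sum also exceeds its typical gene, with 5 of 11 tested genes called higher and a median of 1.02 in H929 (1.66 rescaled), and 3 of 11 and 0.27 in MM1S (0.542 rescaled). The rescaled H2B sum rose by 3.33 in H929 and 2.39 in MM1S on the log2 scale, with all YKL libraries above all DMSO libraries. Division by gene length does not drop out of such a sum, since copies may differ in length. The sum therefore cannot decide whether reads moved between near-identical H2B copies. Of the 11 tested H2B genes, 0 were called lower at 24 h in either line, as deposited or rescaled. A whole-library scale moves all genes alike and cannot give opposite changes of both sums. These changes differed by 5.86 in H929 and 4.58 in MM1S, against SDs of at most 0.35. The pattern was chosen for the opposite changes, so their difference describes it and is no further test. The libraries read polyadenylated RNA, and H2B genes are known to make polyadenylated transcripts in cells that leave the cycle, so a shift in the form of histone transcripts may be the source, as a hypothesis that was not tested.

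Other splits of the samples were compared with the real ones. In each of the 7 comparisons of 3 against 3 libraries, 1 of 10 splits gave as many genes, the real one, and 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 272 and 4 in H929 at 6 h, 4728 and 1 at 24 h, 1360 and 5 in MM1S at 6 h, and 926 and 4 at 24 h. They were 6092 and 1 for H929 against MM1S, 18 and 2 for DMSO over time in H929, and 6982 and 3783 in MM1S. For the interactions 100 splits were drawn after removing the additive effect, which changed the real counts slightly. As many genes were given by 1 split between lines at 6 h (real 21, highest other 3), 3 at 24 h (157 and 2083), 2 between times in H929 (806 and 2245) and 2 in MM1S (10 and 463). Between lines at 6 h only the real split reached its count of 21. That count was 0 without H929 YKL 6 h replicate 2 or without MM1S DMSO 6 h replicate 1. The shuffled groups also mix the responses of both lines, which widens their spread, so the share alone does not decide. In the other 3 interactions the share cannot decide, since single other splits gave far more genes than the real one. The 10 splits of 3 against 3 libraries cannot decide either. Splits with several times the real count, seen in 3 of the 4 interactions, may reflect a structure of the samples other than the treatment. Which structure was not tested, and a single library weighs on it, since without MM1S DMSO 24 h replicate 2 the counts between lines at 24 h and between times in MM1S were 2396 and 323.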

How the results depend on the processing

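Both alternatives that leave out the 3 doubted libraries (H929 YKL 24 h replicate 2, MM1S DMSO 24 h replicate 1 and MM1S YKL 6 h replicate 2) were chosen after seeing the data. Counts of called genes that moved by more than 1.5 times are given here, and the others stayed within that factor. ERCC total scaling and a constant prior variance moved no count by more. For ERCC total scaling this was likely from the start, since the deposited spike-ins were already nearly level across libraries. Rescaling takes out the difference in library scale. On the log2 scale this was -0.841 for YKL against DMSO in H929 at 24 h and -1.194 for MM1S DMSO over time. Beyond that, why a count moved or a direction turned is open, since the cause was not tested. The depth is unknown, so what depth limits could not be said.

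In H929 at 6 h (272 genes) a pseudocount of 0.1 gave 132 and of 5 gave 571, a filter at 5 FPKM 178, rescaling 1155, and quantile normalization 874. Only the groups compared gave 64, leaving out the doubted libraries 439 and that with rescaling 1681. In H929 at 24 h (4728) leaving out the doubted libraries gave 2846. In MM1S at 6 h (1360) no filter gave 832, quantile normalization 2054 and only the groups compared 2457. In MM1S at 24 h (926) a pseudocount of 5 gave 586, rescaling 3447, quantile normalization 3841, only the groups compared 492, and rescaling without the doubted libraries 3519. For H929 DMSO over time (18) a pseudocount of 0.1 gave 5 and of 5 gave 47, rescaling 127 and quantile normalization 87. There, only the groups compared gave 6, and leaving out the doubted libraries 29 and with rescaling 306. For MM1S DMSO over time (6982) rescaling gave 1943, quantile normalization 1825, only the groups compared 3525, and rescaling without the doubted libraries 1112.

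Between lines at 6 h (21) a pseudocount of 0.1 gave 0 in limma (1106 genes at an unadjusted p under 0.05) and of 5 gave 85, no filter 4, and a filter at 5 FPKM 7. Rescaling gave 141, quantile normalization 150, only the groups compared 11, a robust trend 57, and rescaling without the doubted libraries 227. At 24 h (169) the counts were 35 and 679 for the pseudocounts, 107 with no filter, 1536 rescaled, 1729 with quantile normalization, 66 with only the groups compared, 44 without the doubted libraries and 1222 with rescaling. Between times in H929 (803) they were 447 and 1225 for the pseudocounts, 443 with no filter, 1295 rescaled, 1356 with quantile normalization, 483 with only the groups compared, 279 without the doubted libraries and 1503 with rescaling. In MM1S (10) they were 43 for the pseudocount of 0.1, 19 with no filter, 1314 rescaled, 1491 with quantile normalization, 4 with only the groups compared, 34 with a robust trend, 4 without the doubted libraries and 1412 with rescaling.

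Leaving out each library in turn gave 88 to 236 genes in H929 at 6 h, 2844 to 5259 at 24 h, 536 to 1003 in MM1S at 6 h, and 491 to 1861 at 24 h. It gave 0 to 72 and 50 to 2396 between lines at 6 h and 24 h, 273 to 1450 and 1 to 323 between times in H929 and MM1S, 5155 to 5867 for H929 against MM1S, and 9 to 16 and 4560 to 8085 for DMSO over time in H929 and MM1S. The lowest value between lines at 6 h, 0, had 945 genes at an unadjusted p under 0.05 in limma. Over these fits, named genes kept their direction and side of the threshold 1112 times, lost their call 234 times, gained one 4 times and changed sign without a call on both sides 12 times.

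The labels did not say whether replicate numbers pair the samples. Of 21 same-numbered pairs, some of them between lines or times, 4 correlated above 0.1, with a range of -0.206 to 0.21. Pairs with different numbers were not compared, so pairing is not excluded. With the replicate block 148 genes were called in H929 at 6 h, 883 in MM1S at 6 h, 8 and 38 between lines at 6 h and 24 h, 358 between times in H929, 0 in MM1S (1007 at an unadjusted p under 0.05 in limma) and 2 for H929 DMSO over time, and the other counts moved by less than 1.5 times.

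Directions turned for some results. Between lines at 24 h the replication list turned to 0.425 with a pseudocount of 0.1, 0.403 rescaled, 0.663 with quantile normalization and 0.463 rescaled without the doubted libraries, and the G2/M list to 0.20, 0.387 and 0.246 under the last 3. Quantile normalization turned the ATF4 list there to 0.45, ribosomal proteins to 0.00 and oxidative phosphorylation to 0.171 in H929 at 6 h, and oxidative phosphorylation to 0.215 in H929 at 24 h. With no filter the p53, interferon and oxidative phosphorylation lists in MM1S at 6 h turned to -0.188, -0.37 and -0.222. In H929 at 24 h IRF4 turned to 0.58 rescaled, 0.65 with quantile normalization and 0.49 rescaled without the doubted libraries, and MCL1 to 0.74, 0.88 and 0.70. Of 176 list results, 86 lost their call with an estimated correlation and 90 stayed on their side of the threshold. With fry in place of camera 84 stayed, 51 lost their call, 3 gained one and 38 changed direction without a call in both.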

Other observations

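The families and genes in this part, and the test of library scale, were chosen after their values were seen. The percentile test of exon length was set before its result, and the shift of the matched sets was added after it. POLR2A, which encodes the largest subunit of RNA polymerase II, rose in H929 at 6 h from 64.8 ± 11.2 to 140.4 ± 26.5 FPKM. In MM1S it rose from 43.01 ± 4.69 to 112 ± 5.37 FPKM at 6 h and 29.4 ± 14.1 to 67.9 ± 7.85 FPKM at 24 h (SD, n = 3; limma adjusted p 0.0452, 0.00519 and 0.00686 in this order). In H929 at 24 h its log2 change was 0.32 ± 0.29 (adjusted p 0.414), and it rose by 1.14 after rescaling. SNHG1, a host gene of small nucleolar RNAs, fell in all 4 comparisons on both scales, at 6 h from 562 ± 68.9 to 171 ± 44.1 FPKM in H929 and 288 ± 21.5 to 67.2 ± 8.93 FPKM in MM1S. Of 18 SNHG genes, 4 and 12 fell in H929 at 6 h and 24 h and 7 and 7 in MM1S with 0 up. After rescaling 8, 8, 6 and 8 fell and 1, 2, 0 and 1 rose. GAS5, another host gene, fell at 24 h from 1832 ± 88.4 to 435 ± 150 FPKM in H929 and 199 ± 75.8 to 88.9 ± 29.4 FPKM in MM1S on both scales.

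At 24 h, of 14 tubulin genes, 10 fell in H929 and 7 in MM1S as deposited, and 8 fell and 1 rose in each line after rescaling. TUBA1B fell from 4059 ± 1170 to 568 ± 281 FPKM and 1365 ± 801 to 183 ± 67.2 FPKM. Proteasome subunits fell in 33 of 42 in H929 at 24 h, but after rescaling 10 fell and 1 rose, and in MM1S in 2 (10 down and 2 up rescaled). Mitochondrial ribosomal protein genes fell in 68 of 79 in H929 (34 down and 1 up rescaled) and in 6 in MM1S (18 down and 3 up rescaled). Of 172 LINC transcripts, 15 rose and 10 fell in H929 at 24 h as deposited and 42 rose and 0 fell rescaled. In MM1S 2 rose as deposited and 28 rose and 1 fell rescaled. Of all 12418 tested genes, 2585 rose and 1550 fell in H929 at 24 h after rescaling, and 1792 and 1655 in MM1S. The rises of LINC transcripts were thus near the share of all genes, while their falls were fewer. SDC1, the plasma cell marker syndecan, and PRDM1, a plasma cell regulator, were not called at 24 h as deposited (adjusted p 0.539 and 0.65 in H929, 0.0811 and 0.155 in MM1S). Both rose after rescaling, SDC1 by 1.07 and 1.07. CCND1 was at 64.2 ± 7.34 FPKM with DMSO and 37.6 ± 14.5 with YKL in H929 at 24 h, where it fell as deposited (adjusted p 0.0243) and had a rescaled adjusted p of 0.988.

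The families SRSF and HNRNP, which bind pre-mRNA, had medians below that of all genes at 6 h in both lines, in H929 mainly through SRSF. There 2 of 11 SRSF and 1 of 22 HNRNP genes fell (7 and 3 rescaled, with rescaled medians of -0.531 and -0.076), and in MM1S 6 and 12 fell (6 and 10 rescaled). Of their 33 measured genes, 3 fell in H929 and 18 in MM1S as deposited, and 10 and 16 after rescaling, with 0 up, SRSF3 from 191 ± 8.09 to 90.5 ± 15.1 FPKM in H929. After rescaling, the family median lay below that of all genes, at -0.20 from it in H929 and -0.47 in MM1S. A whole-library scale moves the families and all genes nearly alike, and the families were picked for lying low. These values thus describe the pattern and are no further test of that scale. Exon length was checked with 10000 random sets matched on exon length and level, with lengths for 32 of the 33 genes. Among these sets the family median lay at percentile 1.53 in H929 and 0.00 in MM1S. The families were chosen for low values, so a low percentile was likely from the start and does not argue against length. The sets themselves bear more weight: after rescaling they lay -0.077 from all genes in H929 and -0.014 in MM1S, against -0.219 and -0.479 for the families. Exon length and level together can thus account for only a part of the shift in H929. Gene length with introns was not examined. The lower level was not limited to 6 h: at 24 h 28 of the 33 genes fell in H929 and 8 in MM1S, with 15 down in each and 1 and 3 up after rescaling (rescaled medians -0.376 and -0.396). A loss of short-lived transcripts under a block of transcription may be the source, as a hypothesis for which no RNA half-life was tested here.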
